A study of Mus musculus with 6 samples.

How the data were processed

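Gene expression was measured by RNA sequencing of peritoneum from C57BL/6J mice in 6 libraries, 3 from saline-injected controls and 3 from a model of encapsulating peritoneal sclerosis (EPS), a condition in which fibrous tissue encases the bowel. Per the labels' protocols, total RNA was isolated with Trizol, polyadenylated RNA was selected from 3 µg of input with oligo-dT beads, fragmented and copied with random primers, fragments of 400 to 500 bp were kept, and 15 cycles of PCR were run. The protocol names no step that marks strand, so reads from overlapping or antisense genes cannot be told apart here. Per the submitters' processing notes, the genome build was mm10. The aligner, the counting tool and the gene annotation are not given in the sources used here.

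The deposited table holds raw counts of reads per gene symbol, with no normalization, as the whole-number values and the differing library totals show. It lists 14943 symbols, of which 25 had 0 counts in all 6 libraries. Of the symbols, 14673 were found in the GENCODE vM21 annotation of GRCm38, the assembly that mm10 denotes, and 14828 in the RefSeq gene table of GRCm38.p6. Coordinates given in the text are gene bodies from GENCODE vM21, 1-based, and were found for 172 of the 173 named genes. How the authors treated reads that match several genes is not given in the sources used here, so values of near-identical copies (Saa1, Hba-a1 and Hba-a2, Amy2a5, Prss2, Mup3) and of mitochondrial genes with nuclear copies are uncertain.

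From these counts, genes were kept by edgeR's filterByExpr, which left 13980 genes tested and 963 untested. Libraries were scaled by TMM factors and EPS was compared with control by edgeR's quasi-likelihood F-test with robust dispersions (edgeR 4.0.16 in R 4.3.3), with no covariates and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. CPM values, read counts divided by library size, are on TMM-scaled library sizes, the ± of a CPM is the SD over the 3 libraries of a group, and the ± of a log2 fold change is its standard error, the estimate divided by the square root of the F statistic. A fold against a group without any count was computed against a floor of 3 counts over that group, and with 1 to 3 counts the ratio is given with its exact 95% counting interval. Shares of counts in single libraries carry exact 95% Clopper-Pearson intervals. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

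Before the data were examined, 40 gene lists of cell type markers and pathways holding 633 genes were fixed, with no gene in more than 1 list. Of these genes, 598 were in the table. Those not analysed here include Ifng, Il6, Ccl3, Ighm, Ucp1, S100a4 and Cpt1b. Lists were tested with camera (limma 3.58.1) with an inter-gene correlation preset to 0.01 and adjustment over the 40 lists. The camera test asks whether the members rank differently from all other tested genes. The correlation estimated from the data and fry, a test of the list's own genes, were run beside it. The rule for genes named in the text was fixed at the same time: the 12 genes with the largest log2 fold change in each direction among called genes with non-overlapping groups, a mean count of at least 50 and a symbol that is neither predicted nor clone-based nor a V, D or J segment, and up to 4 called members of lowest adjusted p from each list, or the 2 of lowest p where no member was called. Some genes that meet the rule are not reported here. Genes named outside this rule were chosen after their values were seen and are marked so.

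The share of counts taken by the 20 most abundant genes was compared by an exact two-sided permutation test over 20 splits, whose smallest p is 0.1. Library structure was described by Pearson correlations of log2 CPM (prior count of 2) and principal components of the 500 most variable genes. Libraries were also compared in pairs by a chi-square statistic per gene, over genes with at least 20 counts in the pair.

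Depth was even, between 15419232 and 17684229 counts per library. The tests were run on simulated data first. Counts for the real genes were drawn for the EPS against control comparison with a dispersion of 0.05 and 200 genes changed by known folds, and 14167 genes were tested. The edgeR test recovered 8% of the genes changed 1.5-fold, 58% of those changed 2-fold and 100% of those changed 4-fold, with 8 false calls among 13947 unchanged genes. The camera test called a simulated list of 20 genes raised 2-fold and did not call an unchanged list. Simulated genes were drawn independently of each other, so this check does not cover lists of correlated genes. Few genes were changed, with the same dispersion for all and no shift in library composition. The error rates therefore do not carry over to the real comparison, where 59.6% of the tested genes were called. In the real lists the median estimated correlation was 0.24.

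The alternatives were RLE and upper-quartile factors, library totals only, DESeq2 (1.42.0), limma-voom, robust estimation off, no filter and a stricter filter, an adjusted p threshold of 0.01, the replicate number as a block, each library left out in turn, library sizes without muscle, adipocyte and mitochondrial genes, estimated correlation and fry for the lists, and 10 or 50 genes for the share. Averaging controls 1 and 2 into 1 sample, alone or with EPS 1 left out, was added after seeing the data. No per-sample column of the table was left unused. The labels do not say that each library comes from a separate mouse, so p-values measure the spread between these samples, which may be technical in part.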

Results

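The peritoneum, the membrane that lines the abdominal cavity and carries fat depots beneath its surface, was sequenced from male C57BL/6J mice aged 8 weeks. The 3 EPS libraries come from mice injected into the abdomen every day with peritoneal dialysis solution (4.25%, at 100 mL/kg) and 0.3 mL of an agent labelled SHS, and once a week with lipopolysaccharide, a bacterial endotoxin, at 4 mg/kg. The 3 control libraries come from mice given the same volume of saline. Tissue was taken in week 3. The comparison asks which genes differ between the EPS model and saline. The EPS mice received all of these agents, so the separate contributions of the agents are not resolved. Library totals were 16092608, 17684229 and 17246866 counts in controls 1 to 3 and 15419232, 16651797 and 15863775 in EPS 1 to 3.

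The libraries parted by group. The first principal component held 80.5% of the variance of the 500 most variable genes and separated control from EPS, and the second, with 16.4%, set EPS 1 apart from EPS 2 and EPS 3. The lowest correlation of log2 CPM within a group was 0.926 and the highest between groups 0.801. Controls 1 and 2 were closer to each other than any other pair, with a mean chi-square per gene of 4.41 against 15.9 and 16.4 for their pairs with control 3. Sampling noise alone would give about 1. They were counted as 2 samples, as labelled, which leaves open whether they share a source, and results with their mean as 1 sample are given beside the main counts. The 20 most abundant genes took 27.6% ± 0.61 (SD, n = 3) of the counts in controls and 15.1% ± 9.38 in EPS (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The share was 25.97% in EPS 1 (exact 95% interval 25.94 to 25.99), 10.08% in EPS 2 (10.07 to 10.10) and 9.37% in EPS 3 (9.35 to 9.38). In EPS 1, 13.96% of all counts (exact 95% interval 13.94 to 13.98) fell on 10 digestive enzyme and related genes of the exocrine pancreas. Their share was 0.325% (0.322 to 0.327), 0.300% (0.297 to 0.303) and 0.0290% (0.0282 to 0.0298) in controls 1 to 3, 0.0215% (0.0208 to 0.0222) in EPS 2 and 0.0632% (0.0620 to 0.0645) in EPS 3.

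**Figure D1:**
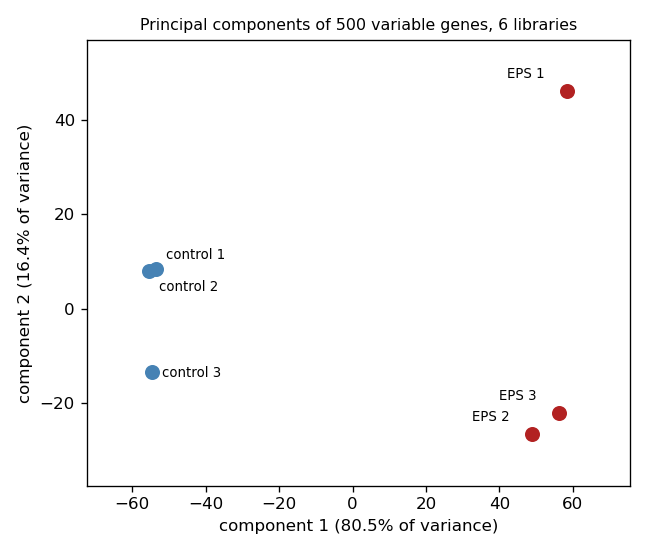
Principal components of the 500 most variable genes, with component 1 on the horizontal axis (80.5% of the variance) and component 2 on the vertical axis (16.4%). Each point is a library, blue for control and red for EPS. The groups lie on opposite sides of component 1, and EPS 1 lies apart from EPS 2 and EPS 3 on component 2.

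Genes of neutrophils, lymphocytes, macrophages, cytokines and the cell cycle were higher in EPS than in control, and genes of fat cells, lipid synthesis, mitochondrial energy metabolism and blood endothelial cells were lower. These lists passed with the preset correlation and none passed with an estimated one, where the lowest adjusted p was 0.0775. All 17 neutrophil genes, 19 T and NK cell genes and 22 cell cycle genes tested rose, and all 18 adipocyte and 18 lipid synthesis genes fell. Genes of collagens, of fibroblasts and of the mesothelium moved in both directions or were not called. Of 13980 genes tested, 4088 were higher and 4245 lower in EPS, and 2416 and 2343 of these had an estimated change of over 2-fold. Without EPS 1, 4393 genes were higher and 4082 lower, and with controls 1 and 2 averaged as 1 sample, 3520 and 3577. The split depended on scaling: with library totals only, 5657 genes were higher (72.2% of calls, against 49.1% with TMM) and 2182 lower. That scaling moved the fold change of the median gene by 0.42 on the log2 scale, and all changes below are relative to the TMM scaling.

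The 12 largest increases by the fixed rule were led by Saa1. Saa1, which encodes the acute-phase protein serum amyloid A1 (chromosome 7, 46740497 to 46742980), had no count in any control library and reached 42.7 ± 25.7 CPM in EPS, at least 583-fold higher. The neutrophil granule genes Ngp (chromosome 9, 110419747 to 110423012) and Ltf, which encodes lactoferrin, rose from 0.202 ± 0.237 to 411 ± 337 CPM and from 0.136 ± 0.0663 to 199.8 ± 155 CPM. Mpo, for myeloperoxidase, had 1 count in the controls and 2756 in EPS, a ratio of 2182 (95% counting interval 391 to 86211). Fpr1, a receptor for formylated bacterial peptides, had 1 control count and a ratio of 1033 (185.1 to 40838). S100a8, a calcium-binding protein of neutrophils and monocytes, rose from 0.0882 ± 0.101 to 85.3 ± 63.0 CPM. No control count was found for the protease gene Ctsg, for Ms4a3, Ceacam10, Mcoln3, the chemokine receptor gene Ccr6 or Sirpb1c, which were at least 313, 114, 110.0, 96.3, 85.8 and 83.1-fold higher. Granule genes varied within EPS: Ngp stood at 132, 315 and 786 CPM in EPS 1 to 3, and without EPS 3 the log2 fold changes of Ngp, Mpo, Ltf and S100a8 were 10.05, 9.36, 9.65 and 8.96 in place of 10.93, 10.59, 10.45 and 9.77. Without control 2, Ngp stood at 12.39, without control 1, Mpo at 12.64, and without control 3, S100a8 at 10.999. The log2 fold change of Fpr1, 9.74, was 11.79 without control 1 and 9.05 without EPS 1. The only control count of Mpo and that of Fpr1 lie in control 1, so their values without control 1 depend on the prior count. The fitted log2 fold changes of Ctsg and Ms4a3, which have no control count and so depend on the prior count, moved from 11.38 to 9.96 and from 9.93 to 8.71 without EPS 3, and that of Ceacam10 from 9.82 to 8.26 without EPS 2. The call for Saa1 was lost without EPS 3 (adjusted p = 0.0534), that for Ceacam10 without EPS 3 (0.0939) and with library totals (0.0691), and that for Ctsg without EPS 1 (0.0507), without EPS 2 (0.106) and with library totals (0.0744); over all alternatives their adjusted p ranged from 1.83e-15 to 0.0534, from 1.18e-05 to 0.0939 and from 3.67e-08 to 0.106. The limma-voom test did not call Mpo (0.0920) or Ltf (0.0664), whose lowest adjusted p over the alternatives were 1.85e-10 and 1.14e-24.

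The 12 largest decreases by the same rule were led by Lctl and Nnat. Lctl fell from 164 ± 27.6 to 2.78 ± 1.13 CPM, which is 57.6-fold lower, and Nnat, which encodes neuronatin, fell from 205 ± 13.2 to 3.77 ± 2.14 CPM. The oxytocin receptor gene Oxtr was 52.4-fold lower and Retnla, which encodes resistin-like molecule alpha, a product of alternatively activated macrophages, was 46.6-fold lower (chromosome 16, 48842551 to 48844461; log2 fold change -6.62 without EPS 2 against -5.54). Pnpla3, for a lipid droplet protein, Rbp4, for retinol-binding protein, and Npr3, the clearance receptor of natriuretic peptides, fell from 416 ± 92.7 to 15.3 ± 4.82, from 413 ± 16.5 to 15.4 ± 7.32 and from 91.3 ± 8.81 to 3.67 ± 1.20 CPM. Slc6a13, Mtarc1, Cdsn, Hephl1 and Coro6 completed the set, at 24.4 to 57.6-fold for the 12 genes. Without 1 EPS library the log2 fold change of Hephl1 moved from -5.41 to -7.06 (EPS 3), of Cdsn from -4.95 to -5.85 (EPS 2), of Slc6a13 from -5.05 to -5.71 (EPS 3) and of Coro6 from -4.72 to -5.41 (EPS 2).

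Of the 40 lists, 21 differed from the other genes by camera with the preset correlation, 12 upward and 9 downward. With the correlation estimated from the data no list passed, 8 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0775. The fry test called 29 lists. Counts of members adjusted over the list alone equalled those adjusted over all genes for 39 lists, and for macrophages were 21 higher and 2 lower.

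**Figure D2:**
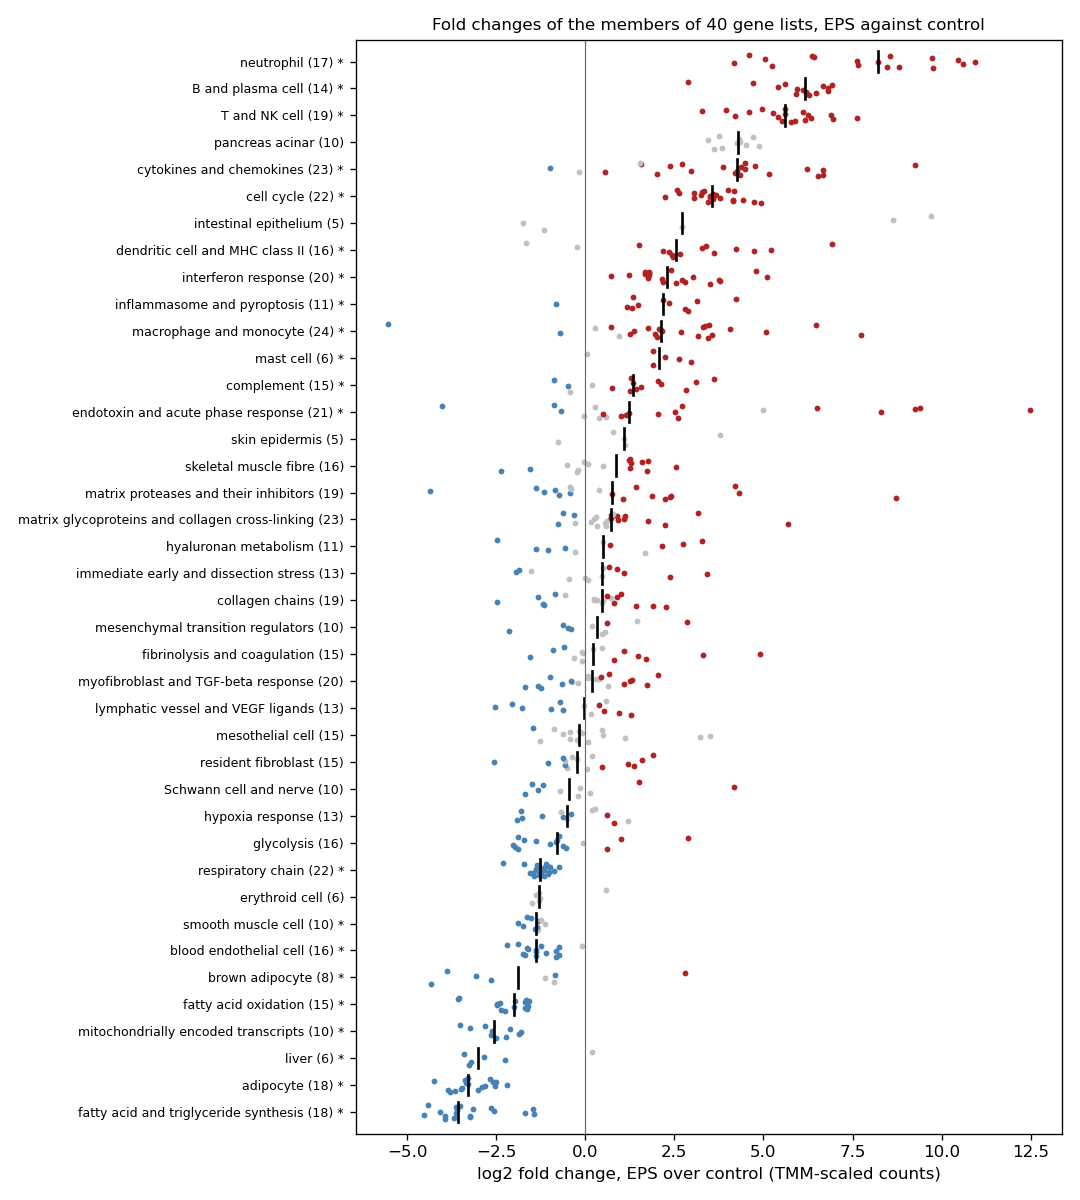
Log2 fold change of EPS over control (horizontal axis) for the tested members of the 40 gene lists (rows, with the number tested). Red and blue points are members called higher and lower, grey points were not called, black bars are list medians and asterisks mark lists that passed camera with the preset correlation. The neutrophil list has the highest median, 8.22, and fatty acid and triglyceride synthesis the lowest, -3.56.

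Markers of white blood cells rose across the lists. All 17 neutrophil genes tested rose, with a median log2 fold change of 8.22, or 7.65 with the gene that had no control count at its bound (camera adjusted p = 1.56e-10; adjusted p = 0.208 with an estimated correlation). Without EPS 3 the fitted median was 7.63. Csf3r, the receptor of granulocyte colony-stimulating factor, rose from 3.58 ± 0.184 to 136 ± 31.0 CPM, and the chemokine receptor gene Cxcr2 from 0.138 ± 0.0742 to 28.7 ± 9.21 CPM. All 19 T and NK cell genes rose, with a median of 5.61 (adjusted p = 5.46e-18; adjusted p = 0.211 with an estimated correlation). Cd8a, the co-receptor of cytotoxic T cells, rose by 6.96 ± 0.37 on the log2 scale and Gzmb, which encodes granzyme B, by 6.12 ± 0.30. All 14 B and plasma cell genes rose, with a median of 6.15 (adjusted p = 1.52e-16; adjusted p = 0.208 with an estimated correlation), among them the B cell receptor partner Cd22 (6.81 ± 0.33) and the IgE receptor gene Fcer2a (6.67 ± 0.23). In controls, 2 of the neutrophil, 5 of the T and NK and 6 of the B cell genes had a mean of at least 1 CPM.

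Macrophage and monocyte genes were expressed in controls and rose further: 20 of 24 were higher and 2 lower, with a median of 2.14 (adjusted p = 7.68e-11; adjusted p = 0.0775 with an estimated correlation). Cd68, a lysosomal protein of macrophages, rose from 26.2 ± 2.49 to 234 ± 12.7 CPM, and Csf1r, the receptor of macrophage colony-stimulating factor, from 133 ± 1.46 to 533 ± 12.9 CPM. The complement components C1qa and C1qb rose by 2.14 ± 0.11 and 2.13 ± 0.10. With any library but EPS 1 left out, 1 member was lower. The 2 members that fell were Retnla and Cd163 (-0.72 ± 0.25), a haemoglobin scavenger receptor of resident macrophages named after its value was seen. Of 16 dendritic cell and MHC class II genes, 14 rose and 2 did not pass, with a median of 2.55 (adjusted p = 3.53e-08; adjusted p = 0.312 with an estimated correlation). The class II transactivator gene Ciita rose by 3.62 ± 0.20, the invariant chain gene Cd74 from 307 ± 61.0 to 1922 ± 388 CPM, and H2-DMb2, which helps load peptides, by 4.72 ± 0.23. Of 6 mast cell genes, 5 rose, with a median of 2.07 (adjusted p = 0.0334; adjusted p = 0.367 with an estimated correlation), including the protease genes Cma1 (2.96 ± 0.34) and Mcpt4 (2.62 ± 0.39). The mast cell list no longer passed without EPS 1 (adjusted p = 0.0575) or with DESeq2 (0.0856), nor with controls 1 and 2 averaged and EPS 1 left out (0.0645), and its adjusted p over the alternatives ranged from 9.31e-04 to 0.367.

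Genes of cytokines and chemokines rose, 20 of 23, and 1 fell (median 4.25; adjusted p = 2.41e-08; adjusted p = 0.142 with an estimated correlation). Ccl5, which attracts T cells, rose from 0.689 ± 0.473 to 69.9 ± 12.2 CPM, and Ccl19, which guides lymphocytes to lymphoid tissue, from 1.18 ± 0.430 to 24.7 ± 5.36 CPM. Il33, an alarmin, rose from 26.1 ± 3.61 to 105 ± 2.93 CPM. All 20 interferon response genes rose (median 2.30; adjusted p = 9.96e-09; adjusted p = 0.309 with an estimated correlation), led by Cxcl10 (4.78 ± 0.27), with the interferon-induced GTPase genes Gbp5 (1.69 ± 0.12), Irgm1 (1.79 ± 0.15) and Igtp (1.80 ± 0.16). In the endotoxin and acute phase list, 13 of 21 genes rose and 3 fell (median 1.23; adjusted p = 7.92e-04; adjusted p = 0.211 with an estimated correlation). Tnfaip3, an inhibitor of NF-kappaB signalling, Tlr2, a receptor of bacterial lipoproteins, and Nfkb2 rose by 2.52 ± 0.13, 2.61 ± 0.17 and 2.03 ± 0.17. Orm1, an acute-phase plasma protein gene that fat tissue also expresses, fell from 269.8 ± 33.3 to 16.6 ± 1.70 CPM. Of 11 inflammasome and pyroptosis genes, 10 rose and 1 fell, and none was lower without control 3 (median 2.17; adjusted p = 1.67e-04; adjusted p = 0.142 with an estimated correlation), among them the DNA sensor gene Aim2 (3.13 ± 0.24) and the adaptor gene Pycard (2.81 ± 0.23). Of 15 complement genes, 11 rose and 2 fell (median 1.34; adjusted p = 0.00118; adjusted p = 0.259 with an estimated correlation), with C4b, a complement component, at 1072 ± 52.2 CPM against 150.3 ± 14.6, and the anaphylatoxin receptor genes C3ar1 (3.11 ± 0.23) and C5ar1 (2.03 ± 0.13).

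Genes of the extracellular matrix moved in both directions. Of 19 collagen chain genes, 7 were higher and 5 lower, and the list did not differ from other genes (adjusted p = 0.801). The fibrillar chains Col1a1 (chromosome 11, 94936224 to 94953042) and Col1a2 rose from 461 ± 34.6 to 2233 ± 782 and from 507 ± 30.3 to 1911 ± 577 CPM, while the basement membrane chain Col4a2 fell from 1454 ± 72.5 to 640.3 ± 86.7 CPM and Col5a3 by 2.49 ± 0.20 on the log2 scale. Of 23 matrix glycoprotein and collagen cross-linking genes, 11 were higher and 3 lower, with a median of 0.71 and adjusted p = 0.0583. This list passed without control 1 (adjusted p = 0.0394), without control 2 (0.0379), without EPS 1 (0.0283) and without EPS 3 (0.00664), with limma-voom (0.0222), with library totals (0.0448) and with controls 1 and 2 averaged (0.0333), with a range over the alternatives from 0.00664 to 0.775. Osteopontin (Spp1), a secreted phosphoprotein also made by macrophages, rose from 0.770 ± 0.275 to 40.3 ± 18.9 CPM, tenascin C (Tnc) from 45.4 ± 10.7 to 215 ± 70.0 CPM, and the genes Cthrc1 and Lum, which encodes lumican, by 3.16 ± 0.47 and 1.75 ± 0.26. Matrix proteases and inhibitors split into 10 higher and 6 lower of 19 (adjusted p = 0.493). The neutrophil collagenase gene Mmp8 rose by 8.72 ± 0.65 (9.996 without control 1) and the lysosomal protease gene Ctss from 31.9 ± 5.73 to 589 ± 26.5 CPM, whereas the inhibitor gene Timp4 fell from 130.0 ± 20.4 to 6.33 ± 0.636 CPM and the aggrecanase gene Adamts5 by 1.37 ± 0.10.

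Genes tied to fibroblast activation were mixed. In the myofibroblast and TGF-beta list, 7 of 20 were higher and 6 lower (adjusted p = 0.704), with 6 and 3 without control 1 and 5 and 3 without control 2. Tgfb1, the cytokine itself (chromosome 7, 25687002 to 25705077), rose from 71.9 ± 5.89 to 237 ± 41.3 CPM, and Ccn4 rose by 2.05 ± 0.32, while Ccn2, which encodes connective tissue growth factor, fell by 1.33 ± 0.24. Acta2, the actin of myofibroblasts and smooth muscle, named after its value was seen, was at 2049 ± 93.7 CPM in controls and 861 ± 470 in EPS (-1.25 ± 0.35, adjusted p = 0.0165). Of 10 mesenchymal transition regulators, 2 were higher and 4 lower (adjusted p = 0.666), with 2 and 2 without control 1 or control 2 and 4 and 2 without EPS 3. The transcription factor gene Runx1 rose by 2.85 ± 0.16 and Cdh2, N-cadherin, by 0.60 ± 0.16. Vim, which encodes vimentin, and Twist1 fell by 0.62 ± 0.14 and 2.14 ± 0.56. With library totals only, neither passed (adjusted p = 0.585 and 0.0559, the highest over all alternatives, whose lowest were 2.93e-04 and 2.85e-04). Without EPS 3, Twist1 did not pass (0.0501), and without EPS 2 it stood at -2.95. Resident fibroblast genes numbered 5 higher and 4 lower of 15 (adjusted p = 0.986; 4 and 8 without EPS 2), with Gsn, gelsolin, falling by 2.56 ± 0.23 and Dpp4 rising by 1.36 ± 0.15; their median of -0.22 was positive (0.24) with library totals, and mean and test had the opposite sign to it. Of 11 hyaluronan genes, 4 were higher and 4 lower (adjusted p = 0.576). The receptor gene Cd44 rose from 25.2 ± 1.74 to 167 ± 16.8 CPM and Itih5 fell by 2.47 ± 0.31. Fibrinolysis and coagulation had 6 higher and 3 lower of 15 (adjusted p = 0.666), with coagulation factor F10 rising by 4.91 ± 0.39, the urokinase receptor gene Plaur by 1.69 ± 0.25, and tissue factor (F3) falling by 1.54 ± 0.15.

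Markers of the mesothelium, the cell layer that covers the peritoneum, were not called by edgeR in 14 of 15 cases (adjusted p = 0.666). These counts rest on EPS 3: without it, 4 were higher and 3 lower. Without EPS 1, 2 were lower. The exception, the tight junction gene Cldn15, fell from 38.3 ± 4.45 to 13.8 ± 1.68 CPM. The list median of -0.18 had the opposite sign to the mean of 0.22, and was positive with library totals (0.21) and without EPS 3 (0.0835). Of 10 smooth muscle genes, 7 fell and none rose (median -1.37; adjusted p = 0.0246; adjusted p = 0.759 with an estimated correlation), with Lmod1 at 165.5 ± 8.11 CPM in controls and 44.4 ± 19.5 in EPS and desmin (Des) at 486 ± 19.3 and 184 ± 70.4. Without EPS 2 the median was -2.09. This list did not pass without EPS 1 (adjusted p = 0.0715; 4.10e-06 to 0.759 over the alternatives).

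Fat cell genes fell together. All 18 adipocyte genes were lower, with a median of -3.30 (adjusted p = 1.38e-10; adjusted p = 0.251 with an estimated correlation). Fabp4, the adipocyte fatty acid-binding protein (chromosome 3, 10204088 to 10208576), fell from 6060 ± 35.4 to 550 ± 100.1 CPM, the lipid droplet genes Plin4 and Cidec from 2783 ± 26.9 to 191 ± 33.8 and from 3337 ± 64.3 to 299.9 ± 58.3 CPM, and the triglyceride lipase gene Pnpla2 from 4139 ± 258 to 407 ± 68.5 CPM. All 18 fatty acid and triglyceride synthesis genes were lower, with a median of -3.56 (adjusted p = 1.30e-08; adjusted p = 0.289 with an estimated correlation). Stearoyl-CoA desaturase 1 (Scd1; chromosome 19, 44394455 to 44407879) fell from 118233 ± 8334 to 7786 ± 2126 CPM. The acetyl-CoA carboxylase genes Acaca and Acacb and the lipogenic transcription factor gene Mlxipl fell by 3.68 ± 0.25, 3.23 ± 0.15 and 3.52 ± 0.23. Brown adipocyte genes numbered 5 lower and 1 higher of 8 (median -1.89; adjusted p = 0.0158; adjusted p = 0.211 with an estimated correlation), with Cidea falling from 79.7 ± 5.21 to 3.86 ± 1.73 CPM. Without EPS 3 the median was -2.51. The limma-voom fit did not call this list (adjusted p = 0.0511; 1.58e-04 to 0.211 over the alternatives).

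Energy metabolism genes were lower as well. All 15 fatty acid oxidation genes fell (median -1.99; adjusted p = 1.38e-10; adjusted p = 0.154 with an estimated correlation), including the dehydrogenase genes Acadm (-2.37 ± 0.11) and Hadh (-2.48 ± 0.12) and Pdk4 (-3.58 ± 0.17), which restrains glucose oxidation. All 22 respiratory chain and citrate cycle genes fell (median -1.27; adjusted p = 1.19e-08; adjusted p = 0.281 with an estimated correlation), with the isocitrate dehydrogenase gene Idh3a at 214 ± 10.8 CPM in controls and 42.9 ± 2.36 in EPS. All 10 mitochondrially encoded transcripts fell (median -2.57; adjusted p = 2.61e-05; adjusted p = 0.378 with an estimated correlation), and mt-Co1 went from 52659 ± 4587 to 8508 ± 2786 CPM. Of 16 glycolysis genes, 12 were lower and 3 higher (median -0.80; adjusted p = 0.0768), with Aldoa falling by 2.04 ± 0.16, Ldha by 1.72 ± 0.15 and Pfkfb3 by 1.88 ± 0.16. The glycolysis list passed without control 1 (adjusted p = 0.0479), without EPS 1 (0.0275), without EPS 3 (0.0206), and with DESeq2 (0.00352) and limma-voom (0.00704), with a range over the alternatives from 0.00352 to 0.765. Of 13 hypoxia response genes, 6 were lower and 2 higher (adjusted p = 0.217; 4 higher without EPS 3), with Bnip3 falling by 1.92 ± 0.14 and Pdk1 by 1.21 ± 0.10.

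Blood vessel genes fell while cell cycle genes rose. Of 16 blood endothelial genes, 15 were lower and none higher (median -1.37; adjusted p = 1.53e-05; adjusted p = 0.211 with an estimated correlation). The angiopoietin receptor gene Tek fell from 110.6 ± 3.67 to 32.9 ± 2.20 CPM, the VEGF receptor gene Flt1 from 221 ± 15.9 to 68.1 ± 4.48 CPM and the guidance receptor gene Robo4 from 140.2 ± 14.7 to 38.0 ± 2.33 CPM. In the lymphatic vessel and VEGF list, 4 of 13 were higher and 6 lower (adjusted p = 0.389), and 2 and 5 without control 1 or control 2. The ligand genes Vegfa and Vegfb fell from 286 ± 29.8 to 83.9 ± 13.2 and from 209 ± 10.6 to 36.2 ± 1.81 CPM, and Prox1, a transcription factor of lymphatic endothelium, rose by 1.28 ± 0.19. The list median of -0.04 was positive with library totals (0.41), RLE (0.0226) and upper-quartile factors (0.00336), and without control 2 (0.00962), control 3 (0.0362), EPS 1 (0.16) or EPS 2 (0.0755). All 22 cell cycle genes rose (median 3.55; adjusted p = 2.38e-19; adjusted p = 0.120 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 2.20 ± 0.155 to 39.4 ± 3.15 CPM, cyclin A2 (Ccna2) from 2.05 ± 0.525 to 43.6 ± 1.57 CPM and the replication gene Mcm5 from 7.60 ± 0.883 to 76.7 ± 9.04 CPM.

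Lists of other tissues and of handling gave the following. None of the 10 pancreatic acinar genes was called by edgeR (adjusted p of the list = 0.801), 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Without EPS 1, 1 of them, Amy2a5, was called lower. EPS 1 held them far above the other libraries. Prss2, a trypsinogen gene (chromosome 6, 41521787 to 41525079), was at 26206 CPM in EPS 1, 22.9 in EPS 2 and 75.1 in EPS 3, against 300 ± 221 in controls, and the list median of 4.28 became -2.86 without EPS 1. None of 5 intestinal epithelium genes was called by edgeR, and 0 had an unadjusted p under 0.05 (adjusted p = 0.986; the median of 2.72 and the test had opposite signs, and the median without EPS 1 was 0.43 over these 5 genes and -0.66 over the 6 genes then tested). It was -0.12 over 6 genes without EPS 2, 0.72 over 6 without control 3, 1.18 over 6 without EPS 3 and 3.48 over 5 without control 1. DESeq2 called 1 of 11 higher and 2 lower, edgeR with robust estimation off called 2 of 5 higher and without a filter 1 of 11 lower, limma-voom called 0, and edgeR called 2 of 6 lower without EPS 1 and 1 of 6 lower without control 3. Reg3b, a secreted lectin of gut and injured pancreas, was at 3158 CPM in EPS 1, 1.17 in EPS 2 and 3.32 in EPS 3, against 1.27 ± 0.320 in controls. Of 6 liver genes, 5 fell (median -3.02; adjusted p = 0.0328; adjusted p = 0.367 with an estimated correlation). These included Cyp2e1, which fat also expresses, from 3708 ± 340 to 522 ± 163 CPM, and Apoc3, from 6.79 ± 1.85 to 0.727 ± 0.152 CPM. The liver list did not pass with DESeq2 (0.0727) or without a filter (0.0850), with a range over the alternatives from 0.00128 to 0.367. Of 16 skeletal muscle genes, 8 were higher and 2 lower (adjusted p = 0.569). The counts were 5 and 1 without control 1, control 3 or EPS 1, 4 and 0 without control 2, and 5 and 2 without EPS 3. Their levels were low, with Ryr1 at 1.62 ± 0.146 CPM in controls and 4.91 ± 0.875 in EPS. Schwann cell and nerve genes numbered 2 higher and 4 lower of 10 (adjusted p = 0.678; the median of -0.45 was 0.0336 with library totals). The counts were 2 and 2 without control 1, 1 and 2 without control 2, 1 and 4 without control 3 or EPS 2, and 1 and 3 without EPS 3. None of 6 erythroid genes was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (adjusted p of the list = 0.704). None of 5 epidermal genes was called by edgeR, where Trp63 and Dsp had an unadjusted p under 0.05 (adjusted p of the list = 0.801). Both were called higher by DESeq2 and without EPS 3. Trp63 was called with RLE factors, with library totals and with library sizes without muscle, adipocyte and mitochondrial genes, and Dsp with robust estimation off and with the stricter filter. Without EPS 1, 0 of these 5 were called and 1 of the 6 genes then tested was, and limma-voom called 0. Alas2, the haem synthesis enzyme of red cell precursors, was at 19.8 ± 14.0 CPM in controls and 7.93 ± 5.62 in EPS, and Trp63, a transcription factor of squamous epithelia, at 2.14 ± 0.402 and 4.57 ± 2.26. Of 13 immediate early and stress genes, 5 were higher and 2 lower (adjusted p = 0.493), with Junb rising by 2.38 ± 0.14 and Dusp1 falling by 1.87 ± 0.25.

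**Figure D3:**
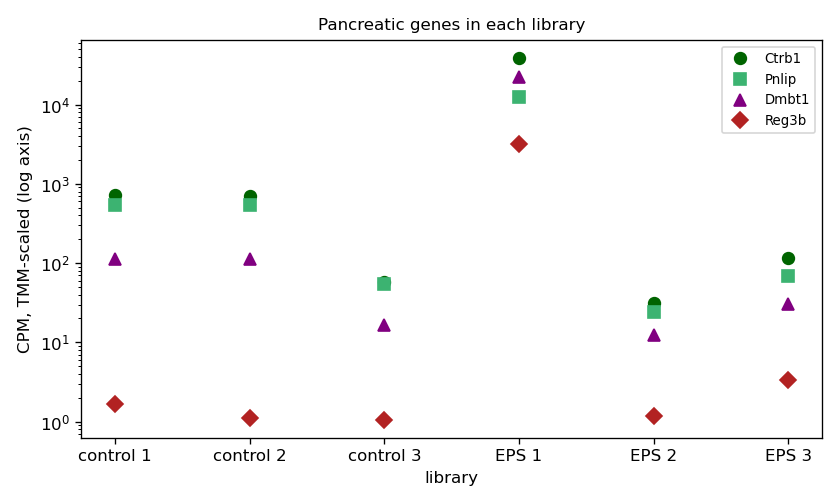
CPM on a log axis of the acinar enzyme genes Ctrb1 and Pnlip and of Dmbt1 and Reg3b in each of the 6 libraries (horizontal axis), each point 1 library; Ctrb1, Pnlip and Dmbt1 were chosen after their values were seen. EPS 1 holds the highest value of each gene, with Ctrb1 at 38703 CPM, and Reg3b lies between 1.06 and 3.32 CPM in the other libraries.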

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

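Both alternatives that average controls 1 and 2 were chosen after seeing the data. The counts of genes higher and lower stayed within 1.5 times of the reported ones in every alternative except library totals, which gave 2182 genes lower, 3625 over 2-fold higher and 1383 over 2-fold lower, in place of 4245, 2416 and 2343. That scaling leaves out the TMM factors. Leaving out 1 library gave 3459 to 4393 genes higher and 3545 to 4155 lower. With an estimated correlation 0 lists passed in place of 21 (8 at an unadjusted p under 0.05), while fry called 29 and leaving out 1 library gave 21 to 23. The cause was not tested beyond the median estimated correlation of 0.24, against the preset 0.01. The 10 and 50 most abundant genes gave differences in share of 13.1 and 12.6 percentage points in place of 12.5, and leaving out 1 library 9.59 to 17.9. For the 50 genes the groups overlapped (exact two-sided permutation p = 0.3). Their share was 33.68% in EPS 1, against 33.49%, 34.42% and 33.28% in controls 1 to 3.

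The gap between the lowest correlation within and the highest between groups was 0.125. It was 0.0781 without a filter, 0.159 with the stricter filter, and 0.115 to 0.159 with 1 library left out, the highest without EPS 1. The lowest correlations within a group were those of EPS 1 with EPS 2 (0.926) and with EPS 3 (0.926), against 0.966 for EPS 2 with EPS 3. Leaving out EPS 1 removes these lowest pairs and so widens the gap. For the other settings the cause was not tested.

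Of 3110 alternative values for the 173 named genes, 3073 kept the direction and the side of the threshold, 22 lost and 11 gained a call, and 4 changed direction. These were Amy2a5 (-2.35 to 4.88 with 1 library left out, and -2.02 with controls 1 and 2 averaged and EPS 1 left out) and Prss2 (-2.52 to 5.46, and -2.17), where EPS 1 sets the direction. Of 798 values for the lists, 724 stayed, 30 lost and 24 gained a call, and 20 medians changed sign, none of a called list. With library totals the medians were 0.24 (resident fibroblast), 0.21 (mesothelial), 0.41 (lymphatic and VEGF) and 0.0336 (Schwann). The lymphatic and VEGF median was 0.0226 with RLE, 0.00336 with upper-quartile factors, 0.0235 with DESeq2, 0.00602 without muscle, adipocyte and mitochondrial genes, -0.30 to 0.16 with 1 library left out, and 0.13 with controls 1 and 2 averaged and EPS 1 left out. The mesothelial median ranged from -0.33 to 0.0835 with 1 library left out. The acinar median ranged from -2.86 to 4.87 and was -2.50 with controls averaged and EPS 1 left out. The intestinal median ranged from -0.66 to 3.48 and was -1.74 with DESeq2 and -1.76 without a filter, which test 11 of its genes in place of 5, as leaving out EPS 1 or EPS 2 tests 6. For the others the cause was not tested.

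Whether the replicate numbers pair the samples was not settled. Deviations from the group means correlated by 0.20, -0.10 and 0.24 for numbers 1 to 3. Controls 1 and 3 correlated best with the EPS library of their own number, and control 2 correlated best with EPS 1 (0.19). With the number as a block, 3947 genes were higher and 4166 lower, 2369 and 2358 over 2-fold, and 21 lists passed; the mast cell list no longer passed (adjusted p = 0.0688), the matrix glycoprotein list did (0.0489), and no named gene changed its call.

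Depth limits the genes near 0 in controls, whose folds rest on 1 to 3 counts or on a floor.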

Other observations

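The groups of genes in this paragraph were chosen after the data were seen. Genes of lymph node stroma and germinal centres, absent from the fixed lists, rose in EPS: 10 of 12 tested were higher and none lower, with a median log2 fold change of 4.31. Glycam1 and Madcam1, adhesion ligands of the vessels through which lymphocytes enter lymphoid organs, rose by 8.23 ± 0.34 and 4.72 ± 0.26, and the lymphotoxin gene Ltb by 5.76 ± 0.40, while Chst4 was not called (0.19 ± 0.32, adjusted p = 0.640). In controls, 6 of the 12 had a mean of at least 1 CPM. Prtn3, a granule protease gene of immature neutrophils, and Cebpe, a transcription factor of their maturation, rose by 5.05 ± 0.87 and 5.75 ± 1.14, while the lysozyme gene Lyz1 (-0.57 ± 0.31, adjusted p = 0.148) and the haptoglobin gene Hp (0.27 ± 0.29, adjusted p = 0.443) were not called. They belong to a list of 9 tested genes, of which 7 were higher and none lower. That count is no independent evidence, since the list holds Ctsg, Ms4a3 and Ceacam10, which were already among the largest increases. Of 76 cytosolic ribosomal protein genes, 70 were higher and none lower, with a median of 0.98 that ranged over the scalings from 0.98 to 1.41. With EPS 3 left out, 1 was lower and the median was 0.86. Rpl3 rose from 336 ± 28.0 to 664 ± 102 CPM and Rps6 from 385 ± 32.7 to 816 ± 110.2 CPM.

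The tests of adipocyte share, of scaling, of read carry-over and of the likeness of controls 1 and 2 in the next 3 paragraphs were chosen only after the result was seen; those of lymphoid tissue and islet genes were written before their genes were looked at. The first pattern is the fall of fat genes beside the rise of immune genes. The scaling of the libraries as the whole cause is argued against, since the adipocyte median was at most -2.83 under 6 scalings. A lower share of adipocytes alone could account for the fall of lipid synthesis genes, whose median differed from that of adipocyte markers by -0.27 (bootstrap 95% interval -0.83 to 0.28). Lower expression within adipocytes could give a like difference, so the 2 medians cannot separate these. Genes within the 2 lists were correlated (estimated 0.51 and 0.48), which the interval may not cover. A lower share of adipocytes alone would raise markers of all other cell types alike. Macrophage and endothelial medians instead moved apart by 3.51, more than the larger interquartile range of 2.11. Both medians were known when this comparison was chosen, so it is no independent test. Vessels may be lost along with fat, so it cannot decide about a loss of fat tissue as a whole. Lymphoid organ tissue in the EPS pieces is consistent with 10 of 12 genes being higher, while lymphoid tissue formed in the model stays open as untested.

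The second pattern is the pancreatic signal. Pancreatic tissue in the EPS 1 piece goes with 13 of 14 islet genes being over 4-fold higher there than in EPS 2 and EPS 3. Chga was the exception, and most genes were at few counts. Ins2 was at 41.2 CPM in EPS 1 against 0.0940 and 0.248 in EPS 2 and EPS 3, and 2.71, 2.38 and 0.132 in controls 1 to 3. The contrast with controls varied by gene. Chgb was at 2.70 CPM in EPS 1 and 2.64, 2.25 and 1.59 in controls 1 to 3, while Pdx1 was at 7.48 CPM in EPS 1 with no control count. Carry-over of reads from EPS 1 into controls 1 and 2 is argued against: scaled by the acinar genes, control 1 and control 2 held at most 0.0208 of the Reg3b that such reads would bring, while the 10 acinar genes lay between 0.644 and 1.85; in EPS 3 the Reg3b share was 0.315. Whether the tissue was dissected along or had adhered to the peritoneum in the model remains open and was not tested. Reg3b and its relatives Reg3a and Reg2, chosen after their values were seen, were at 3158, 1736 and 5568 CPM in EPS 1.

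The third pattern is the likeness of controls 1 and 2. A single library deposited as both is argued against by the mean chi-square per gene of 4.41, where sampling noise gives about 1. Tissue or RNA from 1 source in both is consistent with a largest difference of 0.57 (log2) between them over 16 acinar and erythroid genes, whose median difference from control 3 was 3.28. A like dissection of separate mice stays open as well, and no biological explanation was tested, since the design gives none within controls.

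The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split gave 4088 genes higher and 4245 lower, 2416 and 2343 over 2-fold, and the highest of the other 9 splits gave 0 in each case, so only 1 split reached each count. Each of the other 9 splits mixes control and EPS libraries on both sides, so the group difference adds to the spread within sides. Counts of 0 there were to be foreseen and do not tell how often chance would give the real counts. For the gene lists, 7 of the 10 splits, the real one included, gave 21 or more, the highest of the others being 29. The mixed sides still differ in their number of EPS libraries, so these list counts are no measure of chance either.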
